A study of Homo sapiens with 4 samples.

How the data were processed

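Total RNA of parental T47D cells (2 samples) and of the bone metastatic subline (2 samples) was amplified to cDNA, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The values used were the deposited log2 signals of each probe set, for which the submitters' processing notes name RMA and the affy package. The settings are not given in the sources used here. RMA as usually run corrects the background, gives all arrays the same distribution of probe values and summarises the probes of a set, so a shift of all transcripts in one direction would not be seen in the deposited values. It also compresses differences near background, so folds of dim genes are understated. The values carried 2 decimals, ran from 1.26 to 13.19 and had a median of 3.49 over all arrays, the range of a log2 scale. Scanner files, detection calls and scan dates were not used here, and array batches were not tested. Groups were taken from the labels, and all 4 value columns were used.

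The table held 54715 probe sets, of which 102 Affymetrix control probe sets were left out of all tests. Probe sets were named from the platform annotation, which gave exactly 1 gene symbol for 40914 of the 54613 tested, several for 864 and none for 12835. Gene IDs of 40858 of the 40914 were found in the RefSeq gene table of the human assembly GRCh38.p14, and 0 symbols needed updating. No genome build applies to the deposited values, so no positions are given, and the table served only for names and for the order of neighbouring genes. A gene with several probe sets (10550 of 19774) was represented by the one with the highest mean over the 4 arrays. Probe sets whose names end in _s_at or _x_at can bind several transcripts. Not every named gene read on such a probe set is marked in the text.

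The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, all 4 arrays), with Benjamini-Hochberg adjustment over all 54613 probe sets and a threshold of 0.05 on the adjusted p. The prior had 3.84 degrees of freedom and an SD of 0.156, which with 2 residual degrees of freedom gave 5.84 in all. Permuting the labels of 2 arrays against 2 cannot give a two-sided p below 0.333, so the model's p-values were used. The number of arrays limits the precision. Because of the rounding to 2 decimals, 41 probe sets had identical values within both groups, and their spread came from the prior. The arrays of a group shared identical values for 982 probe sets (parental) and 1096 (subline), against 652 to 905 between groups, so no array was counted as a copy of another.

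In all, 29 gene lists were written down before the data were examined, 25 for pathways and cell states and 4 for other cell types (fibroblast and osteoblast, blood, endothelial and adipocyte). Of 573 list places 536 were measured, and 11 genes stood in more than 1 list. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists, and camera with an estimated correlation and fry were run beside it. The genes named in the text followed a rule set before the data were examined. It took the 12 largest rises and 12 largest falls among genes past the threshold whose arrays did not overlap between groups and whose higher group lay above the median signal, up to 4 members of each list past the threshold with the largest changes (or up to 2 where none passed), and 12 genes fixed in advance (ESR1, PGR, FOXA1, GATA3, ERBB2, RPS6KA5, MAF, CDH1, VIM, MKI67, CXCR4 and NR2F1). This gave 100 genes, of which 82 passed. CXCL12, MYC and OLFM1 are named outside the rule, to complete a count, and were chosen after their values were seen. A further 6 groups of genes were chosen after the results were seen, and appear only among the closing observations, as counts and values without a test of the group. Runs of neighbouring genes were sought as windows of 20 expressed genes whose mean change was compared with 1000 shuffles of gene order.

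The fit and the list test were tried on simulated data with the real arrays' means. Spreads were drawn from the prior that limma fitted, independently of signal, with normal errors. The simulated data thus met limma's own assumptions, so the share of false calls was largely fixed beforehand. The window test was tried on simulated changes not taken from the arrays. With 200 of 54613 probe sets changed, limma called 0% of those changed 1.5-fold, 2% of those changed 2-fold, 96% at 4-fold and 96% at 8-fold, with 5 unchanged probe sets called, and with none changed it called 0. With 5461 changed, as a larger share of the array, it called 25.8%, 82.9%, 99.0% and 99.8% at these sizes, and 4.33% of its calls were false. The list test called the shifted list in 20 of 20 simulated data sets with 0 false calls. Genes were drawn independently there, so this does not show its false calls where list members move together. The window test found 94% of the genes of a segment changed 1.5-fold. It had fewer shuffles than on the data, and a simulated spread below the SD of 0.56 to 1.17 within the real runs, so 94% may be too high.

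For probe sets, genes and gene lists, the alternatives set before the data were examined were eBayes with a trend and a robust prior, a second quantile normalization, centring each array on its median, leaving out dim probe sets or those that can bind several transcripts, the replicate number as a block, a test against a 1.5-fold change (treat), the mean over all probe sets of a gene, adjustment over the representative probe sets alone, the estimated correlation, fry, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.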

Results

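RNA was measured on 4 Affymetrix human expression arrays that carry perfect-match probes, 2 for the parental T47D line and 2 for its bone metastatic subline T47D-5516, which the labels also mark DBM without saying what that stands for. T47D is an established human luminal breast cancer cell line that expresses the estrogen and progesterone receptors. The design sets the line before against the subline after 170 days in a mouse. The lesion from which the subline was taken and its passages afterwards are not given in the sources used here, so the stay, selection and later culture are not separated. The 2 groups give 1 comparison, in which positive log2 changes are higher in the bone subline. The deposited log2 signals had medians of 3.46 and 3.41 on the parental arrays and of 3.52 and 3.56 on the bone subline arrays. Over 54613 probe sets, the SD of the log2 difference was 0.29 between the parental arrays and 0.29 between the bone subline arrays. Between arrays of different groups it was 0.47 to 0.56. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

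The largest differences were rises. TFAP2B, a transcription factor of the AP-2 family, was 65.1-fold higher in the bone subline, with a log2 change of 6.03 ± 0.24 (SE, n = 2 per group, limma adjusted p = 0.0030). Its mean parental signal lay near background, so this fold is not exact and understates the change. CXCR4, the receptor for the chemokine CXCL12, was 40.4-fold higher, with a change of 5.34 ± 0.39 (limma adjusted p = 0.0085). Interferon-stimulated genes rose as a group, with 15 of 26 measured members past the threshold and a median log2 change of 1.19. The list's limma camera test gave an adjusted p = 2.51e-10 (adjusted p = 0.419 with an estimated correlation). TFF3 and TFF1, secreted trefoil peptides induced by estrogen, fell by 2.41 and 1.83 on the log2 scale (limma adjusted p = 0.0132 and 0.0389). PGR, the progesterone receptor, fell by 0.82 (limma adjusted p = 0.0433). Other estrogen receptor targets rose, MYB by 1.35 and CCN5 by 1.25, and the list of 24 was not called (camera adjusted p = 0.0638). ESR1, the estrogen receptor itself, had a change of 0.47 ± 0.13 on its brightest probe set that did not pass (limma adjusted p = 0.0886). Its 7 other probe sets, of which 5 had changes below 0, ranged from −0.17 to 0.24, and none passed.

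Of 19774 genes, 1545 passed an adjusted p of 0.05 in limma, 803 higher and 742 lower in the bone subline. At least 2-fold changes were seen for 500 of the higher and 343 of the lower genes, and at least 8-fold changes for 24 higher and 0 lower genes. Counted by probe set, 3682 of 54613 passed, 1737 higher and 1945 lower. With the replicate number as a block, which leaves 1 residual degree of freedom, 0 genes and 0 probe sets passed. With any 1 of the 4 arrays left out, limma called 0 genes and 0 probe sets at this threshold, against 3225 to 4610 genes at an unadjusted p under 0.05, and 1536 to 1541 of the 1545 genes kept their sign. The genes were chosen on all 4 arrays and each such fit reuses the remaining ones, so agreement in sign was largely fixed beforehand. The balance of calls also moved with the scaling. It went to 805 higher and 1461 lower genes when each array was centred on its median, which moved the median change of all genes from 0.02 to −0.09. It went to 1029 and 597 after cyclic loess and to 918 and 626 after a repeated quantile normalization.

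**Figure D1:**
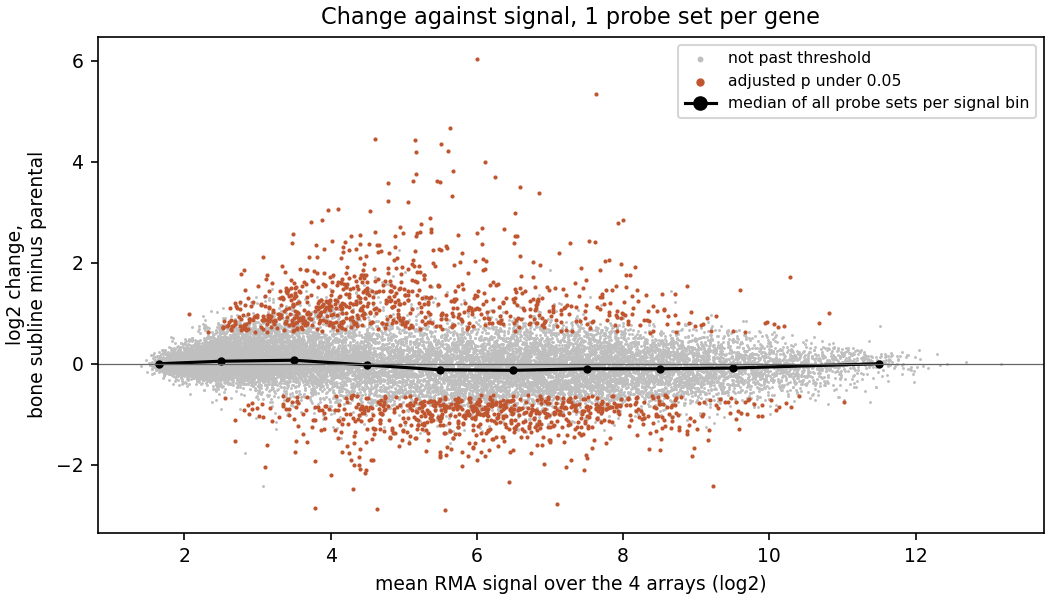
Each point is 1 gene, with its mean signal over the 4 arrays on the horizontal axis (log2) and its change between the groups on the vertical axis (log2, bone subline minus parental). Colour marks the 1545 genes past the limma threshold, and the black line is the median of all probe sets per signal bin, which ran from 0.07 at signals of 3 to 4 down to −0.13 at signals of 6 to 7.

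Among the 12 largest rises, CXCR4 went from a mean signal of 4.96 ± 0.87 (SD, n = 2) in the parental line to 10.29 ± 0.18 in the subline, and both of its other probe sets also passed. AKR1C3, an aldo-keto reductase that acts on steroids and prostaglandins, rose by 4.46 ± 0.21 log2 units (SE, limma adjusted p = 0.0034). DLC1 rose by 4.35 ± 0.37 (0.0113), and 1 of its 4 other probe sets also passed, with a change of 4.57. SERPINE2, a secreted inhibitor of serine proteases, rose by 3.99 ± 0.22 (0.0048). SLC6A14, an amino acid transporter, rose by 3.82 ± 0.40 (0.0154) and KISS1R, the kisspeptin receptor, by 3.71 ± 0.34 (0.0126). MET, the receptor for hepatocyte growth factor, rose by 3.76 ± 0.33 on its brightest probe set (0.0116), whereas its 3 other probe sets, all dim in the parental line, did not pass. SAMD12 rose by 4.42 and ZBTB18, a zinc finger repressor, by 4.21 (limma adjusted p = 0.0016 and 0.0034). MAGEA6, a cancer-testis antigen, rose by 4.66 and OBP2B, an odorant-binding protein, by 4.20 (limma adjusted p = 0.0014 and 0.0067). Both were read on probe sets that can bind several transcripts, so near-identical family members are not told apart. The brightest probe set of DLC1 is also of this kind. Mean parental signals of TFAP2B, AKR1C3 and SAMD12 lay within the range of bacterial control probe sets at background, whose highest value was 3.01, so their folds understate the change. Single parental arrays lay above it, at 3.33 for TFAP2B and 3.02 for SAMD12.

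The 12 largest falls were smaller, from 2.90 log2 units for FAM50B, an imprinted gene, to 2.08 for UAP1L1. FAM50B fell by 2.90 ± 0.21 (SE, n = 2 per group, limma adjusted p = 0.0085), C9orf152 by 2.87 ± 0.14 (0.0034) and MKX, the Mohawk homeobox factor, by 2.86 ± 0.22 (0.0098). MAP6D1 fell by 2.78 ± 0.17 and MMUT, methylmalonyl-CoA mutase, by 2.35 ± 0.14 (limma adjusted p = 0.0053 and 0.0049), each with its other probe set also past the threshold. KCNK5, a potassium channel, fell by 2.48 ± 0.33 (0.0222) and GJA1, the gap junction protein connexin 43, by 2.20 ± 0.26 (0.0185). TBX2, a T-box repressor, fell by 2.16 on its brightest probe set, TGFB3, a TGF-beta ligand, by 2.10, SERPINB1 by 2.10 and UAP1L1 by 2.08 (limma adjusted p = 0.0200, 0.0077, 0.0173 and 0.0106). The 3 other probe sets of TBX2 had smaller changes of −0.27, −0.51 and −0.67 and did not pass. Mean signals of MKX and GJA1 in the subline lay within the range of controls at background, with 1 array of GJA1 above it at 3.03.

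**Figure D2:**
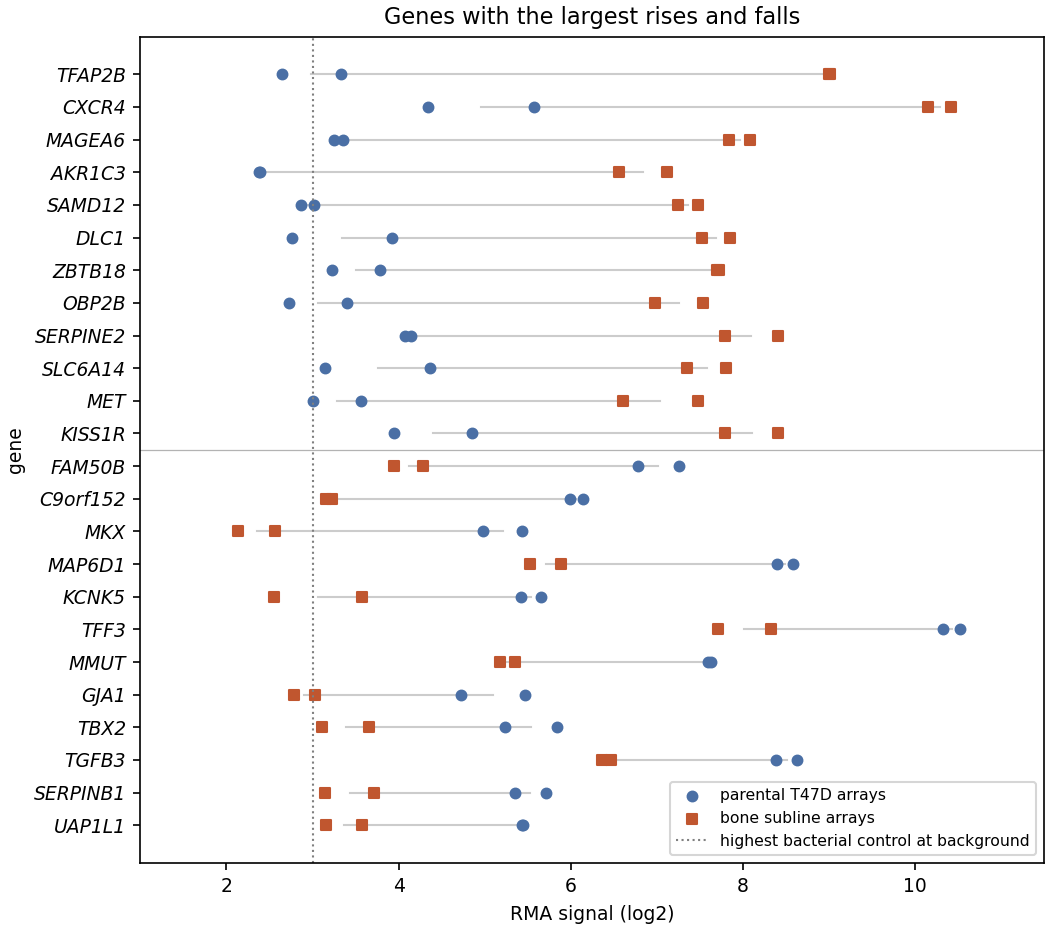
RMA signals (log2) of the 12 genes with the largest rises (upper block) and the 12 with the largest falls (lower block), with 1 circle per parental array, 1 square per bone subline array and a grey line joining the group means. CXCR4 lies at 4.34 and 5.57 on the parental arrays and at 10.16 and 10.42 on the subline arrays, and the dotted line at 3.01 marks the highest bacterial control at background.

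Of 24 measured estrogen receptor targets, 2 rose (MYB, a transcription factor, by 1.35, and CCN5, by 1.25) and 6 fell, namely TFF3, TFF1, PGR, CXCL12, MYC and OLFM1. Counts adjusted over the list alone were 4 risen and 9 fallen. The list's median change was −0.30 and its camera test did not pass (adjusted p = 0.0638). In the luminal epithelial list 3 of 23 members fell and 0 rose, with the same counts when adjusted over the list alone. The list as a whole was not called (median −0.08, camera adjusted p = 0.519). KRT8, a simple epithelial keratin, fell by 1.40 on a probe set that can bind several transcripts, with a parental signal of 9.57. Its only other probe set had a change of 0.14 at signals of 3.70 and 3.84 in the groups, too dim to speak against the fall. SPDEF, an ETS factor of luminal cells, fell by 1.03 and ERBB3 by 0.72 (limma adjusted p = 0.0206 and 0.0427). The luminal factors FOXA1 and GATA3 had changes of 0.35 ± 0.22 and 0.17 ± 0.14 (limma adjusted p = 0.387 and 0.503), with −0.21 and −0.29 on the other 2 probe sets of GATA3. CDH1, E-cadherin, had 0.01 ± 0.14 (0.978) and ERBB2 had 0.04 ± 0.13 (0.905) on their brightest probe sets. The only other probe set of CDH1, with a parental signal of 9.81, had −0.64 ± 0.20, and one of ERBB2 had −0.63 ± 0.19 (limma adjusted p = 0.120 and 0.100). Among 19 basal and myoepithelial genes, CD44 and SOX9 rose by 1.02 and 0.80, and ACTA2 and ITGB4 fell by 1.41 and 0.97. Adjusted over the list alone 6 rose and 2 fell, and the list was not called (camera adjusted p = 0.0638). A dim second probe set of ACTA2 had a change of 0.94 in the opposite direction (limma adjusted p = 0.0263).

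Interferon-stimulated genes had the lowest camera p of the 29 lists at the preset correlation (adjusted p = 0.419 with an estimated correlation). Of 26 measured members, 15 rose and 0 fell, and 17 rose when adjusted over the list alone. SAMD9 rose by 2.53 ± 0.14, IFI6 by 1.92 ± 0.20, IFI44 by 1.86 ± 0.21 and ISG15, a ubiquitin-like modifier, by 1.80 ± 0.14 (SE, n = 2 per group, limma adjusted p = 0.0048, 0.0161, 0.0174 and 0.010). The mean parental signal of IFI44 lay within the range of controls at background and that of SAMD9 at its upper end, with arrays at 2.95 and 3.07. In the antigen presentation list 2 of 16 members rose, PSMB9, an immunoproteasome subunit, by 1.47 and CD74, the MHC class II invariant chain, by 0.93 (limma adjusted p = 0.0206 and 0.0314). Adjusted over the list alone 2 also rose, and the camera adjusted p was 0.0638. Blood cell markers measured on the same arrays had a median change of 0.24 over 15 genes, of which CD3D rose by 0.86 and 0 fell. Adjusted over the list alone 2 rose, and the camera test did not pass (adjusted p = 0.0638).

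**Figure D3:**
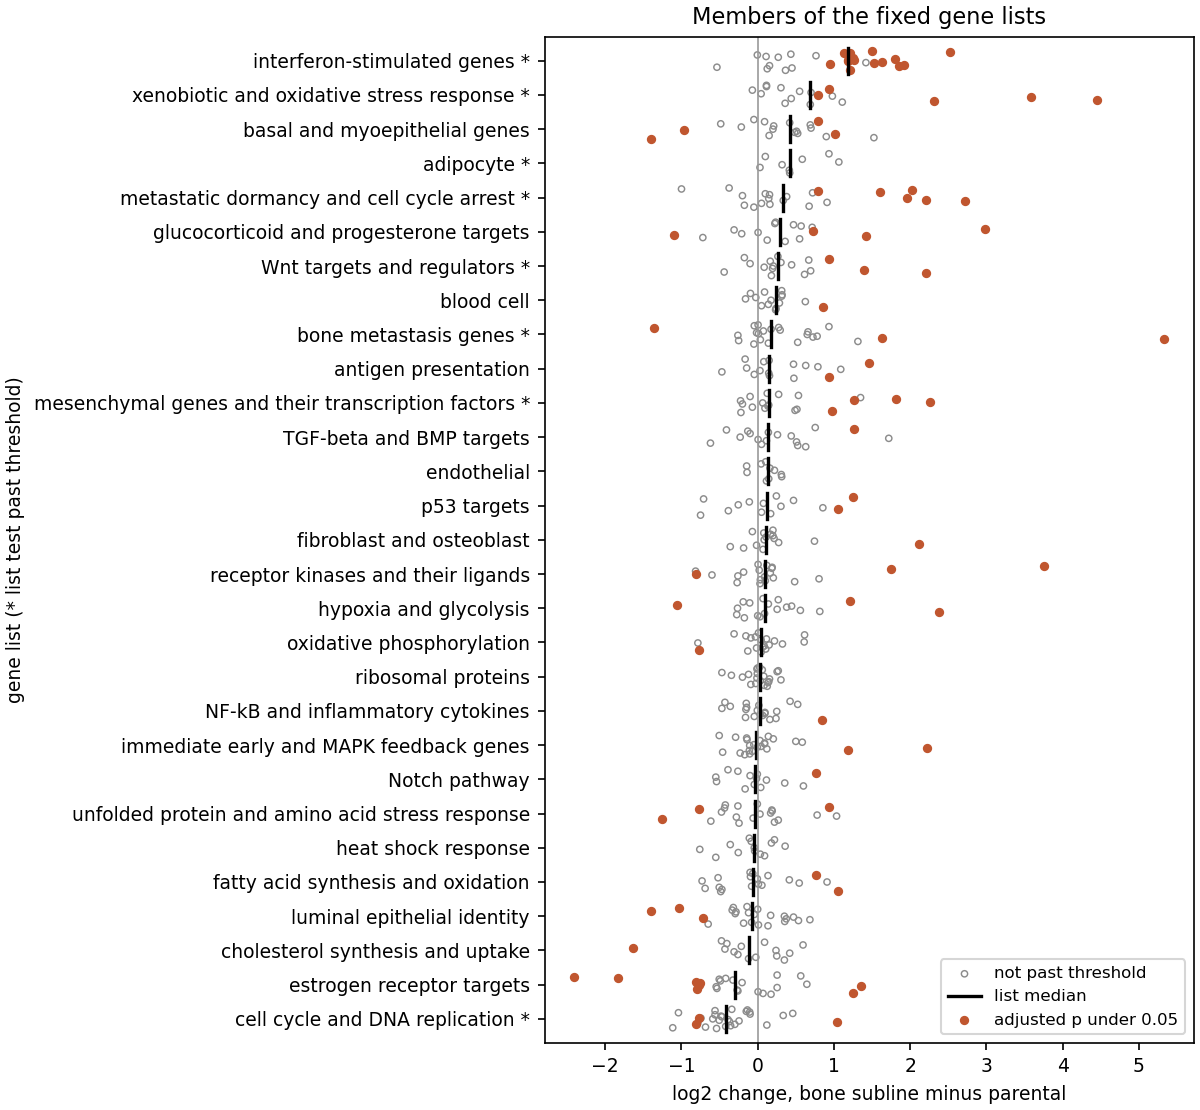
Log2 changes (bone subline minus parental, horizontal axis) of the measured members of 29 gene lists, ordered by median. Filled points passed the limma threshold, open points did not, black bars are list medians and asterisks mark the 8 lists past the camera threshold, with the interferon list at a median of 1.19 and the cell cycle list at −0.42.

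The xenobiotic and oxidative stress list rose, with 5 of 17 members past the threshold and 9 when adjusted over the list alone. Its median was 0.69 (camera adjusted p = 3.16e-05, adjusted p = 0.419 with an estimated correlation). Beside AKR1C3, CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, rose by 3.58 ± 0.42 from a mean signal within the range of controls at background (limma adjusted p = 0.0182). AKR1C1 rose by 2.32 ± 0.40 on a probe set that can bind several transcripts (0.0339), and SLC7A11, the cystine transporter, rose by 0.94 ± 0.17 (0.0394). The 2 other probe sets of SLC7A11, both dimmer, had changes of −0.05 and −0.035 and did not pass.

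Cell cycle and DNA replication genes were lower as a group, with a median of −0.42 and changes below 0 for 25 of 29 members. Their camera adjusted p was 0.000499 (adjusted p = 0.674 with an estimated correlation), and without bone replicate 2 the median was −0.22. Over all genes 2 members fell, CCNB2, a mitotic cyclin, by 0.81 ± 0.15 and MCM3, a subunit of the replicative helicase, by 0.77 ± 0.15 (limma adjusted p = 0.0411 for each). CDC20, an activator of the anaphase-promoting complex, rose by 1.04 from a mean signal within the range of controls at background. Adjusted over the list alone, 1 member rose and 11 fell. MKI67, the Ki-67 antigen, had a change of −0.10 ± 0.15 on its brightest probe set (limma adjusted p = 0.742), whereas 2 of its 3 other probe sets fell, by 1.25 and 0.95 (0.0412 and 0.0366). On the same arrays the signal of ACTB at the 3′ end exceeded that at the middle by 0.49 in the parental line and by 0.73 ± 0.04 (SD, n = 2) in the subline. The same difference for GAPDH was −0.15 ± 0.01 in the parental line and 0.03 ± 0.10 in the subline.

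The metastatic dormancy and cell cycle arrest list rose, with 6 of 21 members up and 0 down over all genes and 10 up and 1 down when adjusted over the list alone. Its median was 0.34 (camera adjusted p = 0.0053, adjusted p = 0.419 with an estimated correlation). CDKN1C, an inhibitor of cyclin-dependent kinases, rose by 2.72 ± 0.21, DKK1, a secreted Wnt antagonist, by 2.22 ± 0.30, TGFB2 by 2.03 ± 0.21 and GAS6, a ligand of TAM receptors, by 1.96 ± 0.24 (limma adjusted p = 0.0089, 0.0224, 0.0154 and 0.0190). All 4 other probe sets of TGFB2 also passed. Other probe sets of CDKN1C with parental signals of 4.62, 4.48 and 4.255, above the 3.585 of the one used, had changes of 0.225, 0.345 and 0.685 and did not pass. The only other probe set of GAS6, with a like parental signal of 5.855, had a change of 0.655 (limma adjusted p = 0.0894). Without probe sets that can bind several transcripts, CDKN1C was read by a dim probe set with a change of −0.02, while a dimmer one rose by 0.85 from background (limma adjusted p = 0.0308), and the list had a median of 0.18 and a camera adjusted p of 0.103. RPS6KA5, the kinase MSK1, had a change of 0.72 ± 0.23 and NR2F1, an orphan nuclear receptor, one of −0.20 ± 0.14 (limma adjusted p = 0.117 and 0.425).

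Bone metastasis genes were called higher as a list, with a median of 0.18 (camera adjusted p = 0.0381, adjusted p = 0.419 with an estimated correlation). That median lay at percentile 97.1 of random lists matched on mean signal, inside their central 95%. Of 23 members 2 rose and 1 fell, or 6 and 1 when adjusted over the list alone. Beside CXCR4, FST, the activin antagonist follistatin, rose by 1.63 ± 0.15, and RUNX2, an osteoblast transcription factor, fell by 1.37 ± 0.14 (limma adjusted p = 0.0126 and 0.0154). The 4 other probe sets of RUNX2 had changes of −0.645, −0.145, −0.77 and 0.295 and did not pass. MAF, a bZIP transcription factor, had a change of 0.66 ± 0.16 from a parental signal of 3.16 ± 0.14 (limma adjusted p = 0.0681). The list's camera adjusted p was 0.0596 without parental replicate 1, 0.0963 without bone replicate 1, 0.287 without probe sets that can bind several transcripts, 0.0675 after repeated quantile normalization and 0.0730 after cyclic loess. Its median was 0.30 without parental replicate 2 and 0.12 without bone replicate 2. The Wnt list was called higher with a median of 0.27 (camera adjusted p = 0.0110, adjusted p = 0.419 with an estimated correlation), at percentile 97.4 of the matched random lists and also inside their central 95%. LEF1 rose by 1.40 and WNT5A, from a mean signal within the range of controls at background, by 0.93 beside DKK1, and these were 3 of 17 members over all genes and 5 when adjusted over the list alone. Its camera adjusted p was 0.0744 without parental replicate 2 and 0.121 without probe sets that can bind several transcripts.

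The mesenchymal list was called higher with a median of 0.15 (camera adjusted p = 0.0184, adjusted p = 0.419 with an estimated correlation). That median lay at percentile 84.2 of random lists matched on mean signal, inside their central 95% of −0.11 to 0.24. Without parental replicate 2 the camera adjusted p was 0.0591 and after repeated quantile normalization 0.0566, and without parental replicate 1 the median was 0.35. Of its 19 members 4 rose, or 5 when adjusted over the list alone, and 0 fell. SPARC, a collagen-binding matrix protein, rose by 2.26 ± 0.29, TNC, tenascin C, by 1.82 ± 0.13, TGFBI by 1.26 ± 0.14 and CALD1, caldesmon, by 0.98 ± 0.17 (limma adjusted p = 0.0205, 0.0083, 0.0162 and 0.0360). Parental signals of TNC and TGFBI were within the range of controls at background. VIM, vimentin, had a change of 0.54 ± 0.18 (limma adjusted p = 0.129). Among markers of other cell types, COL3A1 rose by 2.12 ± 0.19 from background and was the only one of 15 fibroblast and osteoblast markers to pass, also when adjusted over the list alone (list median 0.11, camera adjusted p = 0.226). The 8 adipocyte markers were called higher as a list with a median of 0.42 (camera adjusted p = 0.0346, adjusted p = 0.419 with an estimated correlation). Their camera adjusted p was 0.0589 without parental replicate 1, 0.0868 without parental replicate 2, 0.194 without probe sets that can bind several transcripts, 0.0675 after repeated quantile normalization and 0.0686 after cyclic loess. Over all genes 0 of them passed and 4 did when adjusted over the list alone, and LEP and PPARG had changes of 1.07 and 0.94. Of 10 endothelial markers 0 passed, also when adjusted over the list alone (median 0.13, camera adjusted p = 0.513), and EMCN, within the range of controls at background, and ERG had changes of 0.32 and 0.31.

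None of the other lists passed the camera test, although single members did. Glucocorticoid and progesterone targets came nearest (median 0.30, camera adjusted p = 0.0638), with SLPI, a secreted protease inhibitor, up by 2.98, HSD11B2 by 1.43 and SERPINA1 by 0.73. KLF9 fell by 1.10, and 7 of 16 rose and 2 fell when adjusted over the list alone. Among receptor kinases and their ligands MET and IRS1 rose, IRS1 by 1.75, and FGFR4 fell by 0.81. Adjusted over the list alone 3 of 21 rose and 1 fell (median 0.09, camera adjusted p = 0.587). In the hypoxia and glycolysis list EGLN3, a prolyl hydroxylase, rose by 2.38 and PDK1 fell by 1.06, with a change of −0.06 on the only other probe set of PDK1. SLC2A1 rose by 1.21 on a probe set that can bind several transcripts. Its only other one had −0.19, with mean signals in both groups within the range of controls at background. Adjusted over the list alone 3 of 19 rose and 1 fell (median 0.09, camera adjusted p = 0.201). ETV5 and EGR1 of the immediate early list rose by 2.23 and 1.19 (2 of 24 members, also when adjusted over the list alone, camera adjusted p = 0.912), a list whose median of −0.03 and mean of 0.12 differed in sign. TP53INP1 and GADD45A of the p53 list rose by 1.25 and 1.05 (4 up and 1 down of 14 when adjusted over the list alone, median 0.12, camera adjusted p = 0.503). The 2 other probe sets of TP53INP1 had changes of 0 and 0.23 and did not pass. TGFBI was the only riser of 17 TGF-beta and BMP targets (3 when adjusted over the list alone, median 0.14, camera adjusted p = 0.146). With 1 array left out that median ran from 0.125 to 0.33. CCL2 was the only riser of 20 NF-kB and cytokine genes, by 0.85 from background (1 when adjusted over the list alone, median 0.03, camera adjusted p = 0.791). NOTCH2 was the only riser of 14 Notch pathway genes, by 0.77 (1 up and 1 down when adjusted over the list alone, median −0.03, camera adjusted p = 0.821).

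Metabolic and housekeeping lists gave few calls. MVK, mevalonate kinase, fell by 1.64 and was the only one of 15 cholesterol genes to pass, also when adjusted over the list alone (median −0.12, camera adjusted p = 0.461). ACADM and PPARGC1A rose by 1.06 and 0.77 among 19 fatty acid genes (3 up and 2 down when adjusted over the list alone, camera adjusted p = 0.813), whose median of −0.07 and mean of 0.01 differed in sign. In the unfolded protein and amino acid stress list CHAC1 and SESN2 fell by 1.26 and 0.78 while SLC7A11 rose on its brightest probe set only (3 up and 2 down of 20 when adjusted over the list alone, median −0.03, camera adjusted p = 0.639). ATP5MC1, an ATP synthase subunit, fell by 0.77, the only one of 20 oxidative phosphorylation genes to pass, also when adjusted over the list alone (median 0.05, camera adjusted p = 0.912). Of 13 heat shock genes and 22 ribosomal protein genes 0 passed, also when adjusted over the list alone (medians −0.05 and 0.03, camera adjusted p = 0.519 and 0.862). HSP90AB1 and BAG3 had changes of −0.76 and −0.55, and RPS19 and RPL8 of −0.47 and −0.35 (limma adjusted p = 0.0712, 0.162, 0.169 and 0.198).

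In all, 8 of 29 lists passed camera, 7 higher and 1 lower. With the correlation estimated per list 0 passed, and 1 had an unadjusted p under 0.05. The estimate was below the preset 0.01 for the mesenchymal (−0.046), dormancy (−0.025), Wnt (−0.025), adipocyte (−0.022) and bone metastasis (−0.013) lists. In these lists the loss thus did not come from a higher estimated correlation. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom of the fit. That alone raises p, so in these lists the higher adjusted p does not show that members move together. The estimate was 0.056 for the interferon, 0.092 for the xenobiotic and 0.607 for the cell cycle list. All estimates rest on 2 residual degrees of freedom. The directional fry test, which does not compare a list with other genes, called 6 lists, of which 5 were also called by camera, and did not call the cell cycle, xenobiotic and adipocyte lists. Set against 10000 random lists matched on mean signal, a comparison chosen after the results were seen, the medians of the interferon, xenobiotic, dormancy, adipocyte and cell cycle lists lay outside the central 95%. Those of the mesenchymal, bone metastasis and Wnt lists lay inside. Of the 1545 genes, 616 had another probe set above the median signal, and in 532 of these (86.4%) every such probe set had a change in the same direction. The 82 named genes past the threshold had 133 other probe sets of any signal, of which 41 also passed in the same direction, 1 passed in the opposite direction and 91 did not pass.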

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

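Control probe sets outside the comparison differed between the groups on 2 measures, both of which were computed after the data were seen. The 18 hybridisation spike-in probe sets were higher in the bone subline by a median of 0.49 log2 units (0.11 to 0.57), on both subline arrays in 18 of 18, whereas 27 bacterial controls at background had a median of −0.10. The gap between the 3′ end and the middle of ACTB was 0.24 log2 units wider in the subline, at 0.73 ± 0.04 (SD, n = 2) against 0.49 in the parental line. For GAPDH the same difference was 0.03 ± 0.10 in the subline and −0.15 ± 0.01 in the parental line. From the 3′ to the 5′ end the difference was 0.90 ± 0.01 against 0.75 ± 0.05 for ACTB and 0.51 ± 0.16 against 0.43 ± 0.08 for GAPDH. The arrays of the groups did not overlap on these measures except for GAPDH from the 3′ to the 5′ end, where the parental arrays had 0.37 and 0.48 and the subline arrays 0.40 and 0.62.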

How the results depend on the processing

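The cyclic loess setting and all settings for runs of genes other than leaving out arrays were added after the data were seen. For runs without the signal trend or without probe sets that can bind several transcripts, the test was fixed before its own result was seen. Changes of variance prior, centring, a repeated quantile normalization, cyclic loess and a filter on dim probe sets kept the number of genes within 1.5 times the 1545. With any 1 array left out limma called 0 probe sets, 0 genes and 0 genes changed at least 2-fold (3225 to 4610 genes at an unadjusted p under 0.05). The lone array is then assumed to vary like the other group. Leaving out 1 array gave 5 to 13 lists and 9 to 12 runs. The replicate numbers are shared by the groups, with a correlation of 0.12 between their deviations over 2 pairs (0.20 for probe sets above the median signal), which does not settle a pairing. The fit with the replicate block called 0 probe sets, 0 genes and 0 genes changed at least 2-fold (13976 probe sets and 5674 genes at an unadjusted p under 0.05) and 6 lists, with 1 residual degree of freedom and adjusted p of 0.0727 for the bone metastasis and 0.0501 for the adipocyte list. Against a change of 1.5-fold, treat called 160 probe sets and 97 genes, all 97 changed at least 2-fold. The mean over all probe sets of a gene gave 2600 genes. Without probe sets that can bind several transcripts there were 2181 of 39114 probe sets, 5 lists and 7 runs. The sign turned for CDKN1C (−0.015) and SLC2A1 (−0.19), each then read by a dim probe set, and for KRT8 (0.14), then read by one with signals of 3.70 and 3.84 in the groups. A second, dim probe set of ACTA2 gave 0.94. Repeated quantile normalization gave 5 lists and the estimated correlation 0, with 1 at an unadjusted p under 0.05. The interferon list passed in 13 of 14 alternatives, the cell cycle, xenobiotic and dormancy lists in 12, the mesenchymal and Wnt lists in 11, the bone metastasis list in 7 and the adipocyte list in 5 of 13. Windows of 10 genes gave 6 runs and windows of 40 gave 27. Where no construction is named, the cause was not tested. Signals near 3.01, the highest control at background, limit what dim genes can show.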

Other observations

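The 6 gene groups described first, the genes named in them and among the blood cell markers, the signal-matched random lists, the gaps between replicate arrays, the test of blood cell markers, the test on genes held out of the runs and the other window sizes for the runs were chosen after the results were seen, and the search for runs without the signal trend or without probe sets that can bind several transcripts was added after the data were seen but before its own result. No test of the 6 groups is given, because they were chosen with their members' changes in view. Of 11 STEAP proteins and aldo-keto reductases, 7 rose in the bone subline and 0 fell, with AKR1C3 and AKR1C1 among the risers. The risers AKR1C1, AKR1C2 and AKR7A3 were read on probe sets that can bind several transcripts, so they may not be separate rises. STEAP4, STEAP1 and STEAP2, membrane proteins of one family, rose by 3.33, 2.78 and 2.40 log2 units (limma adjusted p = 0.0031, 0.0053 and 0.0077), whereas STEAP3 had a change of −0.62 ± 0.20 (0.125). Whether STEAP4, STEAP1 and STEAP2 lie in a run of neighbouring genes described below was not examined, so they may not be separate rises. Of 24 secreted products of breast and other glands, 10 rose and 0 fell. The risers OBP2A and OBP2B were also read on such probe sets. SCGB2A2, mammaglobin A, rose by 3.02, SLPI by 2.98, MUCL1 by 1.58 and AZGP1 by 1.47, and PIP, the prolactin-induced protein, rose by 1.01 from an already high signal of 10.32.

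Among 26 cancer-testis antigens 5 rose and 0 fell, with MAGEA6 among the risers. PRAME rose by 1.39 and MAGEA10 by 1.13, and DSCR8 and MAGEA1 rose by 3.50 and 2.55 on probe sets that can bind several transcripts. Of 19 collagen chains 5 rose and 1 fell, with COL27A1, COL21A1, COL5A2, COL9A3 and COL6A1 up by 2.61, 2.60, 1.20, 1.18 and 0.91 and COL9A2 down by 2.00. KLK11 was the only kallikrein of 14 to pass, rising by 3.63. Of 19 integrin chains ITGB1 and ITGB4 fell by 1.84 and 0.97 and 0 rose. ITGB1 was the last gene of a lower run of neighbouring genes on chromosome 10 (MIR1915HG to ITGB1, 30 genes, median −0.535). Its fall may thus not be particular to integrins.

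The rise of interferon-stimulated genes (median 1.19, adjusted p = 0.419 with an estimated correlation) lay above 0.195, the upper limit of the central 95% of random lists matched on mean signal. Without probe sets that can bind several transcripts the median was 0.86 (camera adjusted p = 2.01e-08 at the preset correlation), also above its matched limit of 0.195 and above the gap between replicate arrays of at most 0.08, so these values argue against a signal-dependent shift or cross-binding as the whole cause. Blood cells in the subline samples cannot be told apart from a response of the tumour cells. All 15 markers had a median change of 0.235 with a bootstrap interval of 0.09 to 0.315, which spans 0.237, the bound set for excluding them. With 1 array left out their median ran from 0.11 to 0.325. Of the markers, 4 lay above the median signal. In the subline CD14 had the highest signal of them, 4.51, and HBB, PTPRC and LYZ had 3.50, 2.30 and 2.13, while 0 of the markers stand in another list, the labels name no sort, and RNA of mouse cells would bind these human probes only in part. A lasting effect of the stay in the mouse or of selecting the subline remains open and untested, as does a difference in culture or array handling that follows the groups.

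The fall of cell cycle genes (median −0.42) lay below −0.24, the lower limit of the central 95% of random lists matched on mean signal, which argues against the signal trend as its whole cause. The members moved together between replicate arrays (estimated correlation 0.607, from 2 residual degrees of freedom, adjusted p = 0.674 at it and 0.274 with fry), so a single shared state, such as how densely the cultures had grown at harvest, may lie behind many of them. An effect of 1 subline array cannot be told apart from one of the group, although the bound set beforehand was met (higher camera adjusted p 0.0148 with either left out), because that p assumes the low preset correlation and the median of −0.22 without bone replicate 2 (−0.60 without bone replicate 1) is smaller than the 0.29 between the 2 subline arrays. The labels do not give the growth state, and the higher signal at the 3′ end relative to the middle of ACTB and GAPDH in the subline leaves RNA quality open as well. Slower division of the subline stays a hypothesis that these arrays do not test.

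Along the chromosomes, in the gene order of GRCh38.p14, 11 runs of neighbouring genes (6 higher, 5 lower) held 388 of 12669 expressed genes at windows of 20 genes (79 at windows of 10 and 1752 at windows of 40), among them SPSB2 to DERA on chromosome 12 (62 genes, median 0.62), PHTF2 to GNG11 on 7 (40 genes, median 0.40), FOXD4 to HAUS6 on 9 (27 genes, median −0.84) and PLCXD1 to SCML1 on X (47 genes, median −0.90). The lower runs NYX to XAGE2 and TSPYL2 to FAAH2 were also on X (56 and 23 genes, median −0.73 each). On X, 76 of 378 ordered genes were called lower and 25 higher. The share of genes in the direction of their run was 88.1% over all runs and went from 66.7% (TLCD5 to MSANTD2-AS1 on 11) to 100% (SYTL4 to TCEAL1 on X), with 1 called gene in the opposite direction in each of 2 runs (PLCXD1 to SCML1, and MTMR9 to SH2D4A on 8). Chance order is argued against by 147 of 12232 windows past a limit that 95% of shuffled genomes did not reach, and 8 runs were found with the signal trend removed and 7 without probe sets that can bind several transcripts. A candidate explanation is a difference in copy number between the subline and its parent. Of 302 genes in between, 257 (85.1%, exact 95% interval 80.6 to 88.9) went in the direction of runs defined without them. That interval treats neighbouring genes of 10 runs as independent, which they are not, so it is too narrow. Any change shared by neighbouring genes would also give a high share, so the share does not single out copy number. No DNA was measured, and regulation of neighbouring genes as a domain was not tested, so a difference in copy number stays a hypothesis.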
